A study of Mus musculus with 6 samples.

How the data were processed

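The series holds 6 arrays of total RNA from magnetically separated mouse CD4+CD25+ cells, labelled with biotin in 1 colour. The submitters' genotype labels put 3 in the wild type group and 3 in the Dnmt1 conditional knockout group, and the arrays of a group were numbered by their titles. The deposited values are log2 expression summaries per probe set made with RMA, per the submitters' processing notes. The version of RMA and its settings are not given in the sources used here. RMA sets the background, normalises between arrays and combines the probes of a probe set, so that differences in total RNA per cell are not measured and low transcripts are compressed towards a floor. The deposited log2 values ran from 2.07 to 14.5.

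Probe sets were named through a table of the platform's annotation, whose symbols can be old, and checked against a RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other. Of 22690 probe sets, 64 were controls, 20380 had 1 gene symbol, 691 had several and 1555 had none. Of those with 1 symbol, 20352 were found in the reference table and 1 symbol was updated. Genes without a probe set in this table are unnamed here. Each gene was represented by its brightest probe set, by the mean over the 6 arrays, which gave 12393 genes, of which 4956 had more than 1 probe set. Of the named genes with several probe sets, Dnmt3a, Rps20, Slc4a1, Col1a2 and Xist had another probe set with the opposite sign, whatever its size.

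The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values, with no filter on dim probe sets. P-values were adjusted over all genes by the Benjamini-Hochberg method and called under 0.05, and differences are knockout minus wild type. Tests are two-sided. Errors of group means are SD over 3 arrays. Before the data were examined, 36 gene lists were fixed from textbook knowledge. The 35 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, adjusted over the lists. Member calls were counted over all genes and adjusted over the list alone. Lists share some members, as with Il2ra, Prdm1, Fgl2 and Cd83.

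The genes named were chosen by a rule fixed beforehand, which took 95 genes. It took Dnmt1 and Foxp3, and the 12 called genes with the largest rise and the 12 with the largest fall among genes at or above the median expression with non-overlapping groups, leaving out gene-model symbols and antigen receptor segments. It also took up to 4 called members per list with the lowest p, or the members with the lowest p up to a pair where fewer passed. Genes named outside this rule, chosen after their values were seen, are Ikzf2, Mnd1, Tnfrsf14, Trgv1, Trgv4, Trbv13-2, Igha, Klrb1b, Klra5, Emp1, Tmem176b, Mpo, Prtn3, Kit, Sox13, Il18rap, Brdt, Dppa5a and Il10.

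The tests were tried on simulated data with the real means and spreads and 200 changed genes in each of 20 simulations over 12393 genes. Of genes raised by 0.5, 1 and 2 on the log2 scale, 46.2%, 83.1% and 97.4% were called, and of genes lowered by as much, 46.7%, 85.9% and 97.9%. False calls were 4.9% of all calls. Camera called the shifted list in 100% of the simulations and 0.147% of the unshifted lists, but genes were drawn independently there, which real lists are not.

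Alternatives were quantile normalisation, median centring or cyclic loess of the deposited values, leaving out the dimmest 40% of genes, averaging or separately testing probe sets, trend and robust variance, array weights, a replicate block, a size threshold of 1 on the log2 scale and leaving out each array. The mean of the neutrophil list as a covariate and the germline list without Dazl were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.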

Results

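Transcript levels were measured on 6 oligonucleotide arrays in cells separated to obtain regulatory T cells (Treg). These are the CD4+ T cell lineage that restrains immune responses and whose identity depends on the transcription factor Foxp3. The cells had been separated from mice with magnets as CD4+CD25+ cells, CD25 being the alpha chain of the interleukin-2 receptor. Which share of them expressed Foxp3 cannot be read from these arrays. The knockout group (3 arrays) came from mice with a floxed Dnmt1 gene, which encodes the maintenance DNA methyltransferase, and Cre recombinase under Foxp3. The control group (3 arrays) came from wild type C57BL6 mice. The comparison asks which transcripts differ in the separated cells when Dnmt1 is deleted in those that express Foxp3. The controls are described only as wild type C57BL6. Effects of the Cre or the floxed allele thus cannot be told apart from those of the deletion. The labels call the samples of a group independent without saying that each came from its own animal, so the p-values measure only the spread between these samples. Values are log2 RMA expression of 22690 probe sets, with array medians between 5.78 and 5.84, and the number of arrays limits the precision. Pearson correlations across probe sets, which are not independent replicates, were 0.996 to 0.997 between wild type arrays and 0.991 to 0.993 between knockout arrays. Between the groups they were 0.984 to 0.991, and the first principal component held 58.0% of the variance.

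The targeted gene, Dnmt1, was measured by a pair of probe sets, and both had lower means in the knockout without passing the test. The brighter had a level of 9.50 ± 0.07 in wild type and 8.96 ± 0.34 in the knockout (SD, n = 3), a difference of -0.53 (SE 0.16, limma adjusted p = 0.152). The knockout arrays had values of 8.67, 8.89 and 9.34. The other went from 9.45 ± 0.12 to 8.74 ± 0.39, a difference of -0.72 (SE 0.18, adjusted p = 0.109 over all probe sets). Where these probe sets lie relative to the deleted part of Dnmt1 is not given in the sources used here, and a probe set outside it does not check the deletion. Foxp3, whose locus drives the Cre, had 9.50 ± 0.02 in wild type and 8.84 ± 0.42 in the knockout, a difference of -0.66 (SE 0.19, adjusted p = 0.142). A different knockout array decided each call. Without knockout replicate 3 the Dnmt1 difference was -0.72 (adjusted p = 0.0434), and without knockout replicate 1 the Foxp3 difference was -0.87 (adjusted p = 0.0187). With the mean of the neutrophil marker list on each array as a covariate, a term chosen after seeing the data, the Foxp3 difference was -0.26 (SE 0.45, adjusted p = 0.879).

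**Figure D1:**
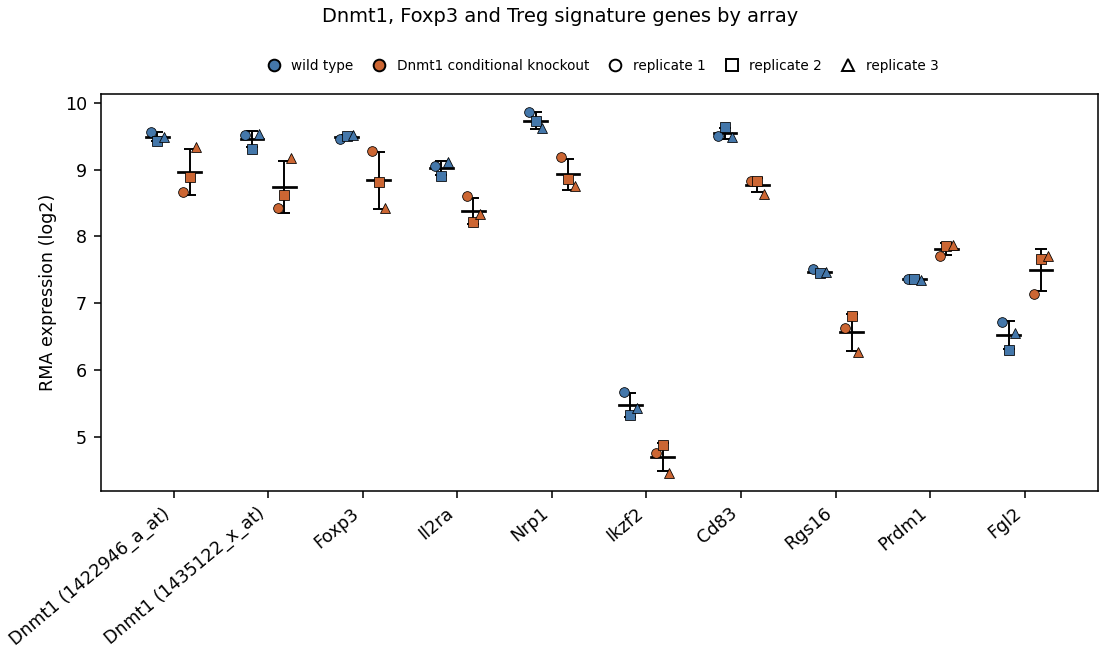
RMA expression (log2) of both Dnmt1 probe sets, Foxp3 and the called Treg signature genes on each of the 6 arrays. Points are arrays, with the replicate given by the shape, horizontal lines are group means and bars are SD (n = 3). The knockout values of Foxp3 spread with an SD of 0.42 against 0.02 in wild type, and Il2ra, Nrp1, Ikzf2, Cd83 and Rgs16 lie below all wild type values.

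Of 12393 genes tested, 165 were higher and 71 lower in the knockout at an adjusted p under 0.05, and 69.9% of the 236 called genes were higher. The gene with the greatest rise was Gdpd3, a glycerophosphodiester phosphodiesterase family member, which went from 5.48 ± 0.31 to 11.73 ± 0.26, a 76.4-fold difference (adjusted p = 1.61e-05). Noct, which encodes the circadian-regulated protein nocturnin, rose 10.8-fold from 7.34 ± 0.16 to 10.77 ± 0.12 (adjusted p = 1.61e-05). Most of the other highly expressed genes with large rises encode granule or antimicrobial proteins of neutrophils: Ltf (24.3-fold), Camp (23.3-fold), Lcn2 (23.0-fold), Ngp (22.8-fold), S100a9 (14.3-fold) and S100a8 (11.03-fold). Slfn4 rose 14.6-fold, Chil3 9.81-fold, the natural killer (NK) cell receptor Ncr1 5.65-fold and Tmem176a 5.60-fold. Chil3 was at -0.11 when the neutrophil list mean was a covariate, but it is a member of that list, so the covariate contains it. Folds are those of RMA values, which compress low levels, so they understate differences of genes near the floor. The falls were smaller, and the deepest among well expressed genes was in Nsg2, from 10.12 ± 0.06 to 8.29 ± 0.76 (3.57-fold lower, adjusted p = 0.0417). The nuclear pore gene Nup210 was 2.67-fold lower, the prostaglandin E receptor gene Ptger2 2.33-fold, Lclat1 2.29-fold and the mitochondrial kinase gene Pink1 2.05-fold. Egr2 and its co-repressor Nab2, part of the transcriptional response to antigen receptor signals, were 1.95-fold and 1.77-fold lower. Galnt10, Spry1, Cd200, Apoe and Rgs16 were between 1.88-fold and 1.92-fold lower. All 236 called genes had knockout values that did not overlap the wild type values, as had 24.98% of all genes, where chance gives 10%.

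These counts fell with each wild type array left out, which also leaves fewer arrays, and moved either way with a knockout array left out. Limma pools the spread of both groups, whose median SD over genes was 0.094 in wild type and 0.123 in the knockout. Without wild type replicate 1, 18 genes were higher and 3 lower, without replicate 2 these were 37 and 7, and without replicate 3 they were 17 and 4. Leaving out knockout replicate 1 gave 358 and 186 genes, and leaving out knockout replicate 3 gave 86 and 29. Of 66 called genes that are named in the text, 8 passed whichever array was left out: Gdpd3, Noct, Dazl, Mnd1, Tnfrsf14, Tmem176a, Lclat1 and Klra8. The calls of 57, 51 and 57 of the 66 were lost without wild type replicates 1, 2 and 3, and those of 1, 16 and 37 without knockout replicates 1, 2 and 3, with no change of sign. With the mean of the neutrophil marker list on each array as a covariate, a term chosen after seeing the data that largely follows the groups, 10 genes were higher and 8 lower, of which 6 and 2 were among the original calls.

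**Figure D2:**
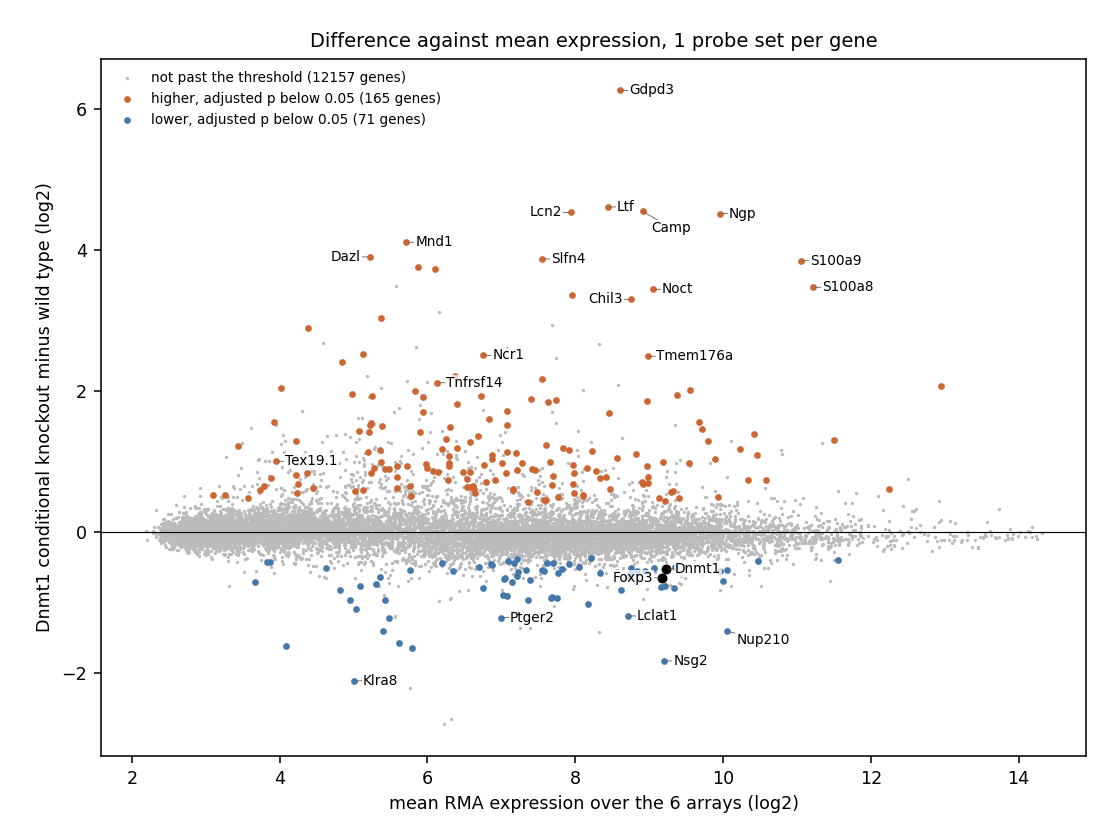
Difference between knockout and wild type (log2) against mean RMA expression over the 6 arrays (log2), with a point per gene. Orange points are the 165 higher and blue points the 71 lower genes at an adjusted p under 0.05, and black points are Dnmt1 and Foxp3, which did not pass. Gdpd3 stands highest with a difference of 6.26, and Klra8 is lowest of the labelled genes at -2.12.

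The Treg signature, genes typical of this lineage, had 32 measured members, of which 5 fell, 2 rose and 25 did not pass. Adjusted over the list alone, 9 were lower and 3 higher. Among the genes that fell were the interleukin-2 receptor gene Il2ra (9.03 ± 0.11 to 8.38 ± 0.20), the semaphorin receptor gene Nrp1 (9.74 ± 0.12 to 8.93 ± 0.23) and Cd83 (9.55 ± 0.08 to 8.77 ± 0.11). Rgs16 was the fourth, and the transcription factor gene Ikzf2 (Helios), singled out after its values were seen, went from 5.47 ± 0.18 to 4.70 ± 0.21. The other Il2ra probe set went from 7.32 ± 0.06 to 7.08 ± 0.18, a difference of -0.24 (limma adjusted p = 0.304 over all probe sets). Prdm1, encoding Blimp1, rose 1.37-fold and Fgl2 1.97-fold. The list was lower by camera (mean difference -0.21, adjusted p = 0.0147), with adjusted p = 0.599 with an estimated correlation. The call was lost without knockout replicate 3 (adjusted p = 0.152) and with the neutrophil covariate (0.0822), where the mean difference was still -0.20. A change within Treg cannot be told apart here from a change in their share among the separated cells. With 1 array left out, the largest adjusted p of the falling genes was between 0.0773 for Cd83 and 0.185 for Il2ra. The core T cell genes, such as Cd28 (10.23 ± 0.11 and 9.85 ± 0.08) and Cd27 (9.74 ± 0.02 and 9.25 ± 0.37), had 0 of 17 members past the limma threshold and 1 lower adjusted over the list alone. Their mean difference was -0.16 (camera adjusted p = 0.0216, adjusted p = 0.599 with an estimated correlation). The list had means of 10.74 to 10.84 on the wild type arrays and 10.85, 10.59 and 10.48 on knockout replicates 1, 2 and 3, and the latter pair also had the highest neutrophil list means. With the neutrophil covariate its difference was 0.12 (adjusted p = 0.297). That call was lost without wild type replicate 3 (adjusted p = 0.0562) and without knockout replicates 2 (0.0874) and 3 (0.302).

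Among the suppressive molecules of Treg, 2 of 17 rose, Lgals3, encoding galectin-3 (3.61-fold), and Fgl2. Adjusted over the list alone 5 were higher, while the list as a whole was not called (camera adjusted p = 0.129). Of the 17, 9 had a positive and 8 a negative difference. The deepest fall was in Il10, from 6.17 ± 0.25 to 4.95 ± 1.01, which did not pass (limma adjusted p = 0.216). Of 20 genes of T cell activation and effector memory, the calcium-binding protein genes S100a6 (2.62-fold) and S100a4 (2.45-fold) and the chemokine receptor gene Cxcr6 (2.26-fold) rose and Il2ra fell, with 5 higher and 2 lower adjusted over the list alone. Camera called that list higher (mean 0.30, adjusted p = 0.0288, adjusted p = 0.540 with an estimated correlation), and 8 of its 20 members ordered the knockout arrays as the neutrophil list did. Of 21 naive and quiescent T cell genes, Bach2, a repressor of effector differentiation, fell 1.47-fold and 0 rose, with 4 lower adjusted over the list alone (camera lower, adjusted p = 0.0391, adjusted p = 0.638 with an estimated correlation). None of 22 effector cytokine genes passed over all genes (0, with 1 higher adjusted over the list alone). Il13 had 4.88 ± 0.23 in wild type and 5.49 ± 0.13 in the knockout, and Csf2 5.37 ± 0.50 and 6.65 ± 0.62. Camera called the cytokine list higher (adjusted p = 0.0288, adjusted p = 0.540 with an estimated correlation), and 9 of its 22 members ordered the knockout arrays as the neutrophil list did. The activation call was lost without wild type replicates 2 and 3 and knockout replicate 2 (adjusted p 0.0562 to 0.140), the naive call without these arrays and knockout replicate 3 (0.0562 to 0.272), and the cytokine call without wild type replicate 2 and knockout replicates 2 and 3 (0.0632 to 0.140). Without knockout replicate 3 the suppressive molecules were called higher (adjusted p = 0.0281). With the neutrophil covariate the direction turned for the activation (mean -0.088), naive (0.16), cytokine (-0.34) and suppressive (-0.11) lists, none of them called.

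Of 23 chemokine and homing receptor genes 1 rose, Cxcr6, with 4 higher and 2 lower adjusted over the list alone (camera higher, adjusted p = 0.0136, adjusted p = 0.540 with an estimated correlation), and 9 of the 23 followed the array order of the neutrophil list. Of 21 chemokine genes 0 passed, also adjusted over the list alone, while camera called the list higher (adjusted p = 0.0209, adjusted p = 0.540 with an estimated correlation) and 11 members followed the array order of the neutrophil list. Of 22 helper lineage transcription factor genes only Prdm1 passed (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.617). Of 16 inhibitory receptor genes, each by its brightest probe set, only Cd200 passed, as lower (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.183). A second probe set of Tox, a member of this list and of the thymocyte markers, was also lower, from 7.57 ± 0.06 to 6.96 ± 0.06 (adjusted p = 0.0185 over all probe sets), where the brightest went from 7.78 ± 0.10 to 7.13 ± 0.25 (adjusted p = 0.0620 over all genes). Among 20 targets of interleukin-2 and STAT5, the kinase gene Pim2 rose 2.13-fold and Il2ra fell (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.656). The homing receptor call was lost without wild type replicate 2 (adjusted p = 0.0508) and knockout replicate 2 (0.0653), and the chemokine call without wild type replicate 3 (0.0562) and knockout replicate 2 (0.174). Without the latter array the inhibitory receptor list was called lower (adjusted p = 0.0197). With the neutrophil covariate the homing receptor (mean -0.055), chemokine (-0.40), helper factor (-0.24) and STAT5 target (-0.13) lists turned negative, as did Pim2 (-0.018), the helper factors being called lower (adjusted p = 0.0397) and the inhibitory receptors too (0.00602).

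Among germline genes normally silenced by DNA methylation, Dazl, which encodes an RNA-binding protein of germ cells, rose from 3.27 ± 0.16 to 7.16 ± 0.25 (adjusted p = 2.83e-05), and Tex19.1 rose from 3.45 ± 0.26 to 4.45 ± 0.24. In wild type 0 of the 22 measured members lay above the median gene, and the higher level of Tex19.1 is close to that of the uncalled members Brdt (4.39 in wild type) and Dppa5a (4.38), so no fold is given. Dazl and Tex19.1 were the 2 members past the threshold, with 4 higher adjusted over the list alone. Camera called the list higher (mean 0.33, adjusted p = 0.000465), with adjusted p = 0.428 with an estimated correlation, and fry, which asks whether the members move on balance to 1 side, gave an adjusted p of 0.00675. The median difference was 0.082, and with Dazl left out of the list, a choice made after seeing the data, the mean of the other 21 members was 0.16 (camera adjusted p = 0.00445, adjusted p = 0.525 with an estimated correlation, fry adjusted p = 0.0405). The call on Tex19.1 was lost without any of the wild type arrays and without knockout replicates 2 and 3 (adjusted p up to 0.151). Of 30 imprinted genes, 0 passed, also adjusted over the list alone (camera adjusted p = 0.774), with Plagl1 at 8.49 ± 0.05 and 7.79 ± 0.46. In the DNA methylation machinery, Gadd45g rose 1.83-fold and the other 16 of 17 members did not pass, including Dnmt3a with 8.39 ± 0.14 and 7.99 ± 0.05 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.618). Of the other Dnmt3a probe sets, 1 was called lower, from 6.92 ± 0.16 to 6.07 ± 0.09 (adjusted p = 0.0166 over all probe sets), and another had a difference of 0.0071 (adjusted p = 0.974). Of 28 histone modifying enzyme genes 0 passed, also adjusted over the list alone, and 22 had a negative difference (camera lower, adjusted p = 0.0288, adjusted p = 0.540 with an estimated correlation). The call was lost without wild type replicate 3 (adjusted p = 0.125), without knockout replicates 1 (0.121) and 2 (0.0653) and with the neutrophil covariate (0.524).

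Of 28 measured genes of the type I interferon response, 4 rose over all genes and 24 did not pass, with 20 higher adjusted over the list alone and 0 lower. The 4 were the exonuclease gene Isg20 (1.59-fold), the deconjugating protease gene Usp18 (1.72-fold) and the oligoadenylate synthetase genes Oas2 (1.98-fold) and Oas1a (1.90-fold). The mean difference was 0.50 (camera adjusted p = 5.37e-12, adjusted p = 0.525 with an estimated correlation, fry adjusted p = 0.116), and 4 members followed the array order of the neutrophil list. With 1 array left out, the largest adjusted p of these genes was between 0.0925 for Isg20 and 0.180 for Oas1a. Of 22 genes of the response to interferon gamma, the GTPase gene Iigp1 rose 1.61-fold, with 2 higher adjusted over the list alone (camera adjusted p = 0.000836, adjusted p = 0.540 with an estimated correlation). Of these 22, 7 followed the array order of the neutrophil list, and with the neutrophil covariate the mean difference was -0.077 (adjusted p = 0.924), while the type I list stayed higher (0.25, adjusted p = 0.0458).

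Markers of other cell types also differed between the groups, above all those of neutrophils. All 17 measured neutrophil markers had a positive difference, 9 passed over all genes and 17 adjusted over the list alone. The mean of the list was 5.89 ± 0.15 in wild type and 8.39 ± 0.98 in the knockout, where replicates 1, 2 and 3 had 7.53, 9.45 and 8.17. Camera gave an adjusted p of 3.27e-16, with adjusted p = 0.525 with an estimated correlation. Of 27 monocyte and macrophage markers, the iron exporter gene Slc40a1 (4.99 ± 0.59 to 6.90 ± 0.12) and the lipopolysaccharide receptor gene Cd14 (3.57 ± 0.09 to 4.86 ± 0.41) rose, with 2 higher adjusted over the list alone. The other Slc40a1 probe set, at 4.11 ± 0.17 in wild type, had a difference of 0.89 (SE 0.18, adjusted p = 0.0644 over all probe sets). The mean difference of that list was 0.73 (camera adjusted p = 1.09e-08, adjusted p = 0.525 with an estimated correlation), and 14 members followed the array order of the neutrophil list. Among 21 CD8 and NK cytotoxic cell markers, the inhibitory receptor gene Klrc1 (3.21-fold), Crtam (2.19-fold) and Ncr1 rose and the NK receptor genes Klra8 (6.06 ± 0.35 to 3.95 ± 0.22) and Klra7 (5.91 ± 0.20 to 4.93 ± 0.18) fell, with 9 higher and 2 lower adjusted over the list alone. Camera called the list higher (adjusted p = 0.00332, adjusted p = 0.584 with an estimated correlation), and 10 members followed the neutrophil order. The other Klra7 probe set, at 3.94 ± 0.02 in wild type, had a difference of -0.0088 (limma adjusted p = 0.972 over all probe sets). With the neutrophil covariate the monocyte call was lost (adjusted p = 0.827) and the CD8 and NK list had a mean difference of -0.41 (adjusted p = 0.0574). Of 12 plasma cell markers Prdm1 and the endoplasmic reticulum gene Creld2 (1.70-fold) rose, with 3 adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.525 with an estimated correlation). Of 20 dendritic cell markers Cd83 and Cd86 (1.75-fold) fell, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.469, mean difference -0.30 with the neutrophil covariate). The other Cd86 probe set, at 5.96 ± 0.14 in wild type, had a difference of -0.22 (limma adjusted p = 0.495 over all probe sets).

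B cell markers had 0 of 19 members past the threshold, also adjusted over the list alone, and a mean difference of -0.15 (camera adjusted p = 0.451), with Cd37 at 10.85 ± 0.07 and 10.66 ± 0.03. That mean difference was positive without wild type replicate 2 (0.15) and without knockout replicate 1 (0.060), and the list was called lower without wild type replicate 1 (adjusted p = 0.0198) and with the neutrophil covariate. Erythroid markers had 0 of 17 members past the threshold and 4 higher adjusted over the list alone (camera higher, adjusted p = 0.000465, adjusted p = 0.540 with an estimated correlation), with Car2 at 6.83 ± 0.08 and 8.53 ± 0.81. Megakaryocyte and platelet markers had 0 of 11 and 2 adjusted over the list alone (camera higher, mean 0.22, adjusted p = 0.0182, adjusted p = 0.525 with an estimated correlation). That call was lost with the neutrophil covariate (adjusted p = 0.0894), though the mean difference did not shrink (0.26). Of thymocyte markers 0 of 13 passed, with 1 lower adjusted over the list alone (camera adjusted p = 0.129), and of stromal and endothelial markers 0 of 16 passed, also adjusted over the list alone (camera adjusted p = 0.478). The sex-linked list had 4 measured genes, too few for camera, and 0 passed, also adjusted over the list alone. Xist was at 11.50 ± 0.14 and 11.34 ± 0.30 and the Y-linked Eif2s3y at 2.49 ± 0.20 and 2.36 ± 0.06 in wild type and knockout.

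**Figure D3:**
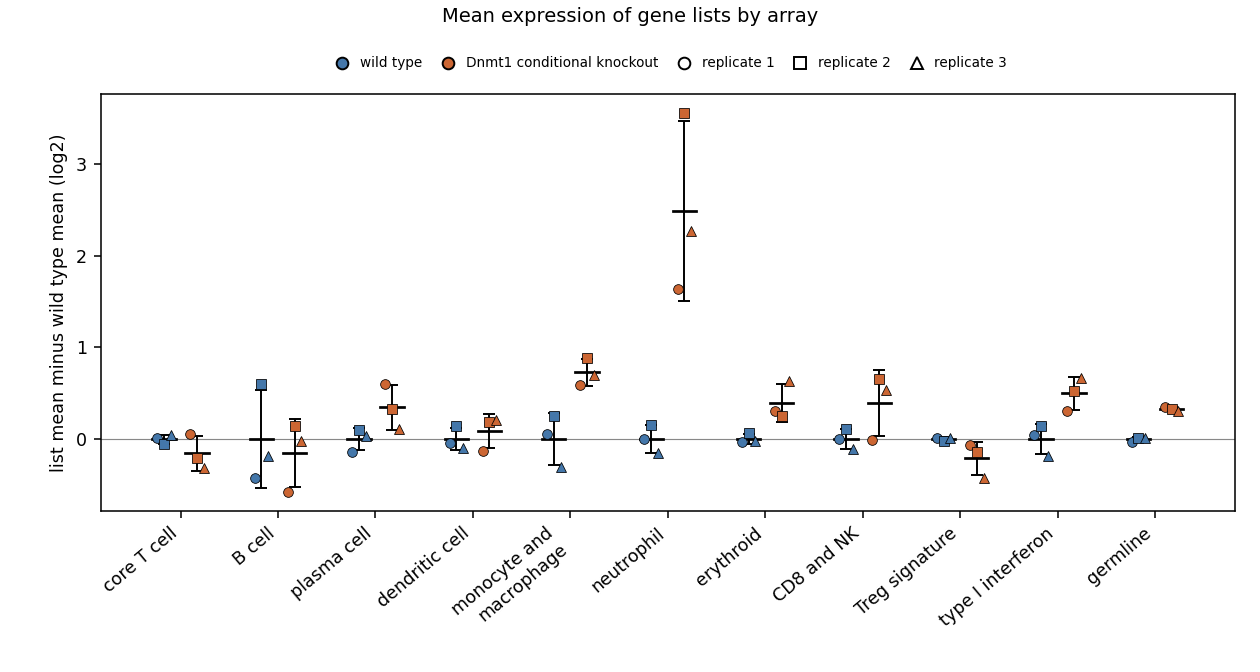
Mean expression of 11 gene lists on each of the 6 arrays, minus the mean of the wild type arrays (log2). Points are arrays, with the replicate given by the shape, horizontal lines are group means and bars are SD (n = 3). The neutrophil list stands apart, with a mean difference of 2.49 and a knockout SD of 0.98, while the germline list has a knockout SD of 0.02.

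Growth and metabolism lists held few calls. Of 41 cell cycle genes 0 passed, also adjusted over the list alone, with Pcna at 11.43 ± 0.04 and 11.61 ± 0.16. Camera called the list higher (mean 0.15, adjusted p = 0.0209, adjusted p = 0.780 with an estimated correlation). Without knockout replicate 3 its mean difference was -0.086, and the call was lost without wild type replicates 2 (adjusted p = 0.160) and 3 (0.0562). Its mean difference was 0.54 with the neutrophil covariate (camera adjusted p = 5.81e-05 at the preset correlation). Without the covariate its estimated correlation was 0.83, and knockout replicates 1, 2 and 3 had list means of 7.29, 7.14 and 7.92. Of 41 ribosomal protein genes 0 passed, also adjusted over the list alone, while 38 had a negative difference with a mean of -0.12 (camera adjusted p = 0.000187, adjusted p = 0.540 with an estimated correlation), which was 0.028 with the neutrophil covariate (adjusted p = 0.582). Of 19 cholesterol biosynthesis genes 0 passed, also adjusted over the list alone (camera lower, adjusted p = 0.0209, adjusted p = 0.599 with an estimated correlation), a call lost without wild type replicate 1 (0.0608) and knockout replicates 2 (0.140) and 3 (0.0572) and turned to higher with the neutrophil covariate (mean 0.25, adjusted p = 0.0390). The apoptosis regulator genes Casp1 (2.28-fold) and Bik (2.09-fold) rose among 24 measured, with 3 adjusted over the list alone (camera adjusted p = 0.451). Of 24 p53 target genes Sesn1 fell 1.47-fold, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.880). Of 25 immediate early and heat shock genes only Egr2 passed, as lower (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.691). Of 20 glycolysis genes 0 passed, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.774). Of 51 oxidative phosphorylation genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.979), and the mean (-0.0055) and median (-0.014) of their differences had the opposite sign to the camera test. With the neutrophil covariate this list was called higher (mean 0.20, camera adjusted p = 5.81e-05). The immediate early and heat shock list was called lower there (mean -0.27, camera adjusted p = 0.0321). These calls too used the preset correlation, while the estimates without the covariate were 0.45 and 0.12. In all, camera called 14 of 35 lists higher and 6 lower with its preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Fry called 1, with 9 at an unadjusted p under 0.05. Its mixed form, which counts change of either sign and compares no list with the other genes, called 27. The 6 lists lower became 3 without wild type replicate 3, 3 without knockout replicate 2 and 2 without knockout replicate 3.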

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

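The tests on neutrophil transcripts, on the 5 genes with the lowest p and on Klra7 and Klra8 were chosen after those results were seen, and the splits of the arrays were chosen before. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real split, gave as many called genes as the 236 observed, and the highest of the other splits gave 0. The same held for the 165 higher and the 71 lower genes, with 1 split and a highest other of 0. For the gene lists called by camera with its preset correlation, 1 split reached the real 20, and the highest other split called 17. With 10 splits, no share under 0.05 can be had. The other splits mix arrays of both groups, so they are no clean measure of chance.

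Probe sets without a single gene name entered no comparison in the report. Of these 2246 probe sets, 39 were higher and 9 lower in the knockout than in the wild type arrays. That share is close to the 236 of 12393 among the genes tested. Of the 64 control probe sets limma called 0, with 17 at an unadjusted p under 0.05. This is a larger share than the 2222 of 12393 genes tested, and its cause was not tested.

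Neutrophil markers stood on average 2.49 above wild type on the log2 scale, and all 3 knockout arrays lay above all wild type arrays. The tables argue against a lower share of T cells that raises every other cell type alike, since the neutrophil list rose by 2.64 (SE 0.46) more than the B cell list, whose 19 markers had no call. Neutrophils among the separated cells are a candidate source, and the abundant S100a8 and S100a9 reached 12.95 and 12.97. Of 17 markers, 16 put the knockout arrays in the order of the mean of the other markers. Random lists matched on mean expression, 10000 in all, had a median of 3 and at most 11 (permutation p = 1e-04, the lowest possible). Such lists hold unrelated genes, so the test shows that the markers moved as a set and cannot name their source. The first principal component had the same order on knockout replicates 1, 2 and 3 (7.23, 28.89 and 16.90). Separation for CD4 and CD25 would be meant to remove neutrophils, and 6 of the 17 markers lie above the median gene already in wild type. Whether knockout mice held more neutrophils or the separations differed cannot be read from these arrays, and the genotype stays open as an untested biological explanation.

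Gdpd3, Noct, Mnd1, Dazl and Tnfrsf14 had the lowest p of all genes and little spread in the knockout. RNA of neutrophils is argued against: between knockout replicates 1 and 2 the neutrophil list differed by 1.92, while the mean of these 5 genes differed by -0.16 (SE 0.06 over the genes); choosing genes by a low p favours a small spread, but the 17 markers differed by 0.72 to 3.04 between these arrays and the 5 genes by -0.35 to -0.036. A chromosome segment of another strain around Dnmt1 is argued against too, since 0 of the 5 lie among its 50 measured neighbours, of which 1 was called (Fisher's exact p = 0.619). Segments elsewhere in the genome and strain variants under single probes were not tested. Loss of silencing after deletion of Dnmt1 may be the cause as a hypothesis, but no methylation was measured in the data used here.

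Klra8 and the brighter probe set of Klra7 fell while other NK receptor genes rose. The dimmer Klra7 probe set differed by -0.0088. Whether the falling probe sets tell these receptor genes apart was not checked, so the falls of Klra8 and Klra7 may not be independent. The other 19 markers of NK and CD8 T cells had a mean difference of 0.60 (SE 0.19 over the markers). On its own that mean argues against fewer NK or CD8 T cells. The markers are not independent replicates, though, and 10 of the 21 in the list followed the neutrophil order. With the neutrophil covariate the list was at -0.41 (camera adjusted p = 0.0574), so fewer of these cells are not excluded. Another strain haplotype at the NK receptor cluster could give falls and rises side by side: 5 of the 50 measured neighbours of Klra8 were called (Fisher's exact p = 0.00250), but these include Klra7 and Klrc1, whose calls prompted the test, and of the 46 outside the marker list 3 were called (Klrb1b, Klra5 and Emp1, all higher, p = 0.0544). By the limit first written, a p of 0.05 or more, that would count against the explanation; the limit was changed after this p was seen, as 3 genes are too few to exclude a cause, and the explanation is left open, also because receptor genes of the same cells lie there and would move with a change in cell mix. The labels give C57BL6 for both groups, and an effect of Dnmt1 on these genes stays open as an untested biological explanation.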

How the results depend on the processing

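The neutrophil covariate and the germline list without Dazl were chosen after seeing the data, and all other alternatives before. Depth here is signal over background: genes near the floor have compressed differences. Counts of higher and lower genes ranged from 17 to 358 and from 3 to 186 with 1 array left out, lists higher from 10 to 14 and lists lower from 2 to 6. Dnmt1 ranged from -0.72 to -0.38 (adjusted p 0.0434 to 0.360) and Foxp3 from -0.87 to -0.45 (adjusted p 0.0187 to 0.339); the cause was not tested. Lower genes numbered 113 with trend and robust variance and 110 with array weights, and lists lower numbered 1 with dim genes left out; the cause was not tested. A size threshold of 1 left 79 higher and 12 lower genes by construction. Camera with an estimated correlation called 0 lists higher and 0 lower. The germline list and the megakaryocyte and platelet list had estimates of -0.019 and -0.041, below the preset 0.01. Their calls were lost all the same, with camera p going from 7.92e-05 to 0.0122 and from 0.00625 to 0.0455. A higher correlation between members thus cannot explain the loss for these lists, and the cause was not tested. Same-numbered arrays had correlations of deviations of -0.082, 0.147 and -0.041, and 1 of 3 arrays correlated best with its own number. With 3 arrays a group this check neither shows nor excludes a pairing by number. The replicate block gave 112 genes higher and 35 lower. Dnmt1 and Foxp3 had a negative difference under every alternative run, but with the neutrophil covariate Foxp3 was at -0.26 (SE 0.45, adjusted p = 0.879) and Dnmt1 at -0.64 (SE 0.40, adjusted p = 0.627).

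With the neutrophil covariate, which mostly follows the groups, 10 genes were higher and 8 lower. By camera at its preset correlation, 7 lists were higher and 4 lower. Signs turned for Chil3 (-0.11), Csf2 (-0.13), Ccl5 (-0.051), Ccl17 (0.063), Plagl1 (0.43), Pmaip1 (-0.19), Pim2 (-0.018), Ndufa5 (0.068), Sqle (0.15), Cd27 (0.11), Prtn3 (-0.051), Trbv13-2 (0.23) and Kit (-0.19). Chil3 and Prtn3 are members of the neutrophil list, so the covariate contains their own values. Camera's direction turned for suppressive molecules (mean -0.11), cytokines (-0.34), helper factors (-0.24), activation (-0.088), naive genes (0.16), homing receptors (-0.055), chemokines (-0.40), interferon gamma (-0.077), p53 targets (-0.055), apoptosis (-0.069), STAT5 targets (-0.13), cholesterol (0.25), ribosomal proteins (0.028), core T cell genes (0.12), CD8 and NK markers (-0.41), dendritic cells (-0.30) and stroma (-0.078). Of these, helper factors (adjusted p = 0.0397) and cholesterol (0.0390) passed in the new direction. The cause was not tested.

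Camera's direction also turned for oxidative phosphorylation with median centring (-0.039) and averaged probe sets (-0.02). With some array left out it turned for the same list, whose mean ranged from -0.039 to 0.039 over the 6 fits, and for glycolysis (-0.021 to 0.034), p53 targets (0.028 to 0.072), B cells (-0.36 to 0.15), helper factors (0.013 to 0.14), STAT5 targets (0.012 to 0.10) and cell cycle (-0.086 to 0.30), and the difference of Xist ranged from -0.29 to 0.0045. The cause was not tested.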

Other observations

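Trgv1, Trgv4, Trbv13-2, Igha, Mpo, Prtn3 and Tmem176b were singled out after their values were seen. The gamma delta T cell receptor segments Trgv1 and Trgv4 were higher in the knockout, from 8.40 ± 0.21 to 10.34 ± 0.62 and from 8.89 ± 0.35 to 10.44 ± 0.54 (SD, n = 3), with limma adjusted p of 0.0243 and 0.0423. The beta chain segment Trbv13-2 had 7.65 ± 0.07 in wild type and 6.94, 4.20 and 3.83 on the knockout arrays and did not pass (adjusted p = 0.121). Igha, the constant region of immunoglobulin A, rose from 11.91 ± 0.64 to 13.98 ± 0.43 (adjusted p = 0.0303). The early granule genes Mpo (4.01 ± 0.14 to 5.96 ± 0.80) and Prtn3 (4.46 ± 0.14 to 5.98 ± 0.62), both members of the neutrophil list, rose, as did Tmem176b (4.02-fold). With 1 array left out, the largest adjusted p was 0.126 for Trgv1, 0.180 for Trgv4, 0.107 for Igha, 0.164 for Mpo, 0.186 for Prtn3 and 0.0566 for Tmem176b.

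Of the 165 higher genes, 55 (33.3%) ordered the knockout arrays as the neutrophil list did, and of the 71 lower genes 9 (12.7%), where chance gives 16.7% and all genes gave 18.9%. In the reverse order were 21 of the lower genes. The neutrophil list itself held 9 of the higher genes. The first principal component ordered the knockout arrays alike, so this order is not particular to neutrophils.

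The tests of both hypotheses that follow were chosen before their results were seen, but 1 part of their reading was not. The criterion set beforehand was a camera p under 0.05 with a positive mean difference, and both lists met it. A further requirement, that no other split of the arrays reach as low a p, was added after these values were seen, because other splits did reach it. Those splits mix knockout and wild type arrays, so a real difference that varies between knockout arrays can also give a low p there. They are thus no measure of chance. Neither list had a p under 0.05 by camera with an estimated correlation, and both hypotheses are left open.

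Gamma delta T cells or innate lymphocytes among the separated cells may explain the rise of Trgv1 and Trgv4, though separation for CD4 and CD25 would be meant to remove most of them. A list of other genes of these cells had 5 measured members, among them Sox13, Kit and Il18rap, all with a positive difference and 0 past the limma threshold. Its mean difference was 0.73 (camera p = 0.00344, p = 0.160 with an estimated correlation), and 3 of the 9 other splits gave a camera p under 0.05, the lowest 5.44e-05.

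A rise of germline genes in general could go with the rise of Dazl and Tex19.1. A further list of germline genes, with none of the first, had 24 measured members, 18 with a positive difference and 0 past the limma threshold. Its mean difference was 0.12 (camera p = 0.0125, p = 0.111 with an estimated correlation), and 2 of the 9 other splits gave a camera p under 0.05, the lowest 0.00757.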
